A study of Mus musculus with 18 samples.

How the data were processed

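Libraries were made by multiplexed reduced representation bisulfite sequencing of MspI-digested genomic DNA, per the labels' protocols. The 18 deposited files have no header and list 1 CpG per line with the number of methylated reads over the number of all reads at that CpG, on genome build mm9 per the submitters' processing notes. Aligner, methylation caller, duplicate handling and read filters are not given in the sources used here. In 11 files the lines have 4 columns. In the other 7 (day 16 pregnant progenitor, all day 19 and all retired libraries) they have 6 columns, with a strand and a score that the authors deposited beside the reads; the score equals 1000 times the methylated share within rounding (largest difference 0.5) and was used only for that check. Nothing says that reads were pooled between libraries. Files listed 1328066 to 1479376 CpGs each, fewest in the day 19 libraries, and 1485193 CpGs in any library. Single CpGs reached 2730305 reads.

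Samples were grouped by the cell type and stage in their labels into 9 groups of cell type by reproductive state. CpGs with at least 5 reads in all 18 libraries were kept (711980), so that every library was measured at the same CpGs, and methylated and total reads were summed per 1000 bp tile with at least 3 such CpGs (77064 tiles, median 4 CpGs). Each tile was fitted with a quasi-binomial logistic regression, with the dispersion moderated across tiles as in limma's squeezeVar and held at 1 or above, and tested with an F test and Benjamini-Hochberg adjustment over all tiles of a comparison. A tile was called at an adjusted p under 0.05 and a difference of mean methylation of at least 10 percentage points. All 18 libraries entered each fit and shared one estimate of the spread. Cell types and the virgin stages were compared in a model of cell type plus stage, and pregnancy and retirement in a model of the 9 groups. The 13 tile comparisons were each adjusted on their own. Mean levels were compared by exact permutation of libraries, within stages for cell types. Context of called tiles was tested with Fisher's exact test. These choices, the groups, the rule for named tiles and most alternatives were fixed before the data were examined; the CpG class of 20 to 80%, the similarity of libraries, the fit of 4-column files alone and the thinning of reads were chosen after seeing the data.

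Among called tiles whose virgin and pregnant libraries did not overlap, the 5 with the largest rise and the 5 with the largest fall were named by coordinate. The gene table at hand is on build GRCm38.p6, while the files reach position 197193526 on chromosome 1 of mm9. Its coordinates were therefore not used, no gene was assigned to a tile, and the planned tests of promoters and gene lists were not run.

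The alternatives were a minimum of 10 reads, tiles of 500 bp, a difference of 20 points, any CpG with 5 reads in a library, removal of CpGs above the 99th percentile of coverage, removal of the X, Y and mitochondrial chromosomes, limma on log2((methylated + 1)/(unmethylated + 1)) with trend and robust moderation, models without stage or without interaction, and leaving out each library in turn. Where a group was left with 1 library, that library was assumed to vary like the other groups.

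The test was tried on simulated counts with the depths of these libraries and 200 of 77064 tiles changed. Changed tiles had middle levels, and changes were cut short near the ends of the scale, so some set to 40 points were smaller. Apart from these changes all libraries shared the same level at a tile, with no structure of stages or libraries. For pregnancy in stem cells the test recovered 13% of tiles changed by 20 points and 68% of those set to change by 40 points, with 1 false call. For stem against mature cells it recovered 47% and 90%, with 7 false calls, and for pregnancy averaged over cell types 78% and 96%, with 5 false calls. The analysis used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1 and statmod 1.5.0.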

Results

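DNA methylation was measured in 18 reduced representation bisulfite libraries of mouse mammary epithelium, a method that cuts genomic DNA with the enzyme MspI at CCGG sites and so reads mainly CpG-rich parts of the genome. Cells labelled as stem, progenitor or mature were purified from C57BL/6 females at 6 reproductive stages: virgin mice at week 3 and week 9, pregnant mice at day 10, day 16 and day 19, and retired breeders. Each stage gave 1 library per cell type. For each cell type there were therefore 2 virgin, 3 pregnant and 1 retired library, and the stages served as the replicates. The labels do not say whether libraries came from separate animals or whether the cell types of one stage shared animals. The p-values therefore measure the spread between these libraries. For pregnancy and retirement that spread includes differences between stages of the same state, while cell types were compared within stages. Reads summed over CpGs ran from 17513287 in the retired mature library to 117922522 in the week 9 virgin mature library, with a median coverage per CpG of 10 to 70 reads. The shallowest libraries were retired progenitor and retired mature (median 10 reads), day 16 progenitor (11), retired stem (13) and day 16 stem (14). All comparisons used 711980 CpGs with at least 5 reads in all 18 libraries, summed into 77064 tiles of 1000 bp with a median of 208 reads per tile and library. Reads may include PCR copies of one molecule, and the intervals given below treat tiles as independent.

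The first question was whether the overall methylation level differed between cell types or with pregnancy. At the CpGs shared by all libraries, mean CpG methylation lay between 49.2% and 51.2% in the 18 libraries. The range was wider where libraries were not held to the same CpGs and weights. It was 44.97 to 50.98% over all CpGs with 5 reads in a library. With reads pooled over all CpGs listed for a library it was 42.45 to 52.66%. The 3 day 19 libraries were the lowest on both scales. Stem libraries averaged 50.1% ± 0.629 (SD, n = 6), progenitor libraries 50.6% ± 0.328 (n = 6) and mature libraries 50.6% ± 0.469 (n = 6). Paired by stage, stem minus progenitor was -0.487 points (two-sided exact permutation p = 0.125), stem minus mature -0.523 points (exact p = 0.188) and progenitor minus mature -0.036 points (exact p = 0.906), none larger than the spread between stages. Leaving out 1 stage moved these values: stem minus mature was -0.802 points without week 9 and -0.3325 points without day 19, and progenitor minus mature was 0.122 points without week 3 and -0.183 points without day 10. Pregnant stem libraries averaged 49.6% ± 0.432 (n = 3) against 50.7% ± 0.372 (n = 2) in virgin stem libraries, a difference of -1.06 points (exact p = 0.2). In stem cells it was -0.715 points over all CpGs with 5 reads in a library (exact p = 0.8). With reads pooled over the shared CpGs it was -0.553 points (exact p = 0.8). As a mean over the shared CpGs, the difference between pregnant and virgin libraries was 0.176 points in progenitor cells (exact p = 0.6). In mature cells it was -0.179 points (exact p = 0.8). It became 0.404 points in mature cells without the week 3 virgin library and -0.762 points without the week 9 virgin library, and ran from 0.039 to 0.407 points in progenitor cells, without day 10 and without day 19. With 3 libraries against 2 there are 10 splits, so no such p can be below 0.1. Among the 118570 CpGs with a mean level of 20 to 80%, a class set after the data were seen, all 3 pregnant stem libraries (53.0 to 55.3%) lay below both virgin stem libraries (58.1% and 59.4%), a difference of -4.84 points (exact p = 0.1, the smallest possible). At these CpGs the difference was 0.83 points in progenitor cells (exact p = 0.2) and -0.508 points in mature cells (exact p = 0.7).

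**Figure D1:**
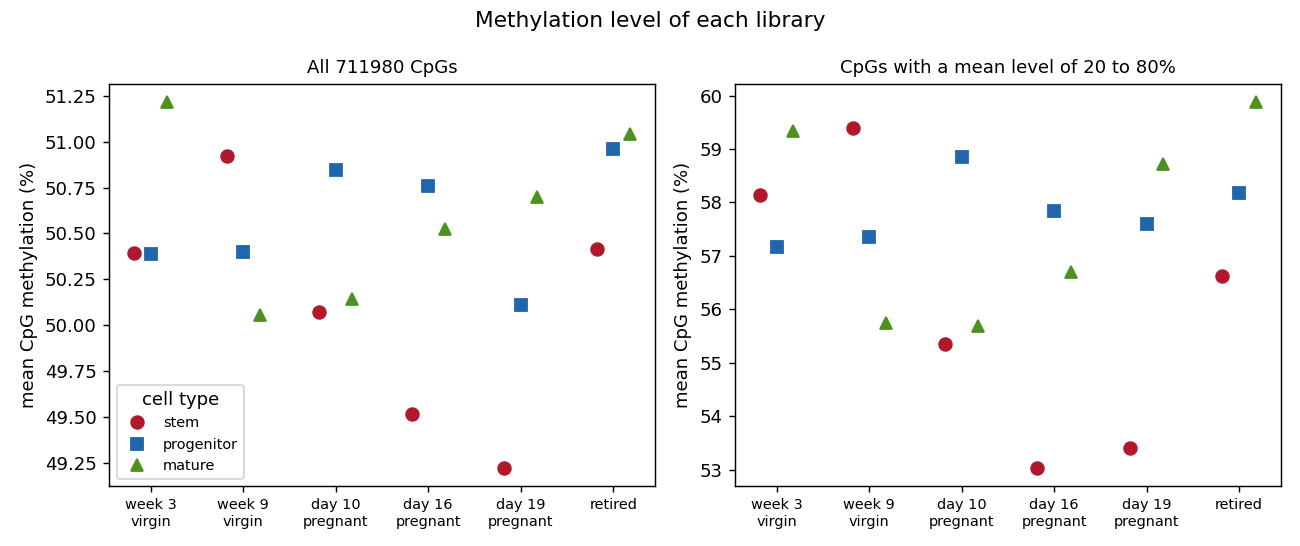
Mean CpG methylation in percent (vertical axes, not starting at 0) of each of the 18 libraries by stage, with 1 point per library and the marker giving the cell type, over all 711980 CpGs on the left and over the CpGs with a mean level of 20 to 80% on the right. On the right, the 3 pregnant stem libraries lie at 53.0 to 55.3% and the virgin stem libraries at 58.1% and 59.4%.

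Pregnancy in stem cells, the comparison named in the title of the study, was the only one of the 13 tile comparisons with called tiles. In pregnant stem cells 237 of 77064 tiles differed from virgin stem cells, and 175 of them had less methylation while 62 had more. The labels give ages only for the virgin mice, so an effect of age cannot be told apart from one of pregnancy. All 3 pregnant stem libraries also had fewer reads (median 121 to 213 per tile) than both virgin stem libraries (249 and 321), so depth differed along with pregnancy. The 175 falling tiles averaged 56.6% in virgin and 26.5% in pregnant stem libraries, and the 62 rising tiles 48.1% and 73.9%. The median change was -27.3 points in falling and 24.9 points in rising tiles, and 40 tiles changed by at least 40 points. Most called tiles, 67.5%, had a mean level of 20 to 80%, against 22.0% of the other tested tiles; a call needs a change of at least 10 points, so tiles near 0 or 100% could hardly be called and the shares are given only as a description. Only 1 of the 237 lay in a tile with 20 or more CpGs, but within the class of 20 to 80% called and other tiles did not differ in CpG number (3 to 9 CpGs in 96.2% and 95.6%, Fisher's exact test, adjusted p = 0.873). The test was a quasi-binomial logistic regression with dispersion moderated across tiles, and the smallest adjusted p was 0.0269.

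The count of stem cell tiles depended on single libraries and on depth. It was 1 without the week 9 virgin library, 0 without day 10 or without day 16, 800 without the week 3 virgin library and 214 without day 19; it was 43 with at least 10 reads per CpG, 26 in tiles of 500 bp, 441 when each library contributed any CpG with 5 reads, 0 with limma on log2 ratios of methylated to unmethylated reads, and 0 after thinning all libraries to the depth of the shallowest. In the 11 files with 4 columns alone, which hold 2 pregnant and 2 virgin stem libraries, 184 tiles were called, of which 49 were among the 237.

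**Figure D2:**
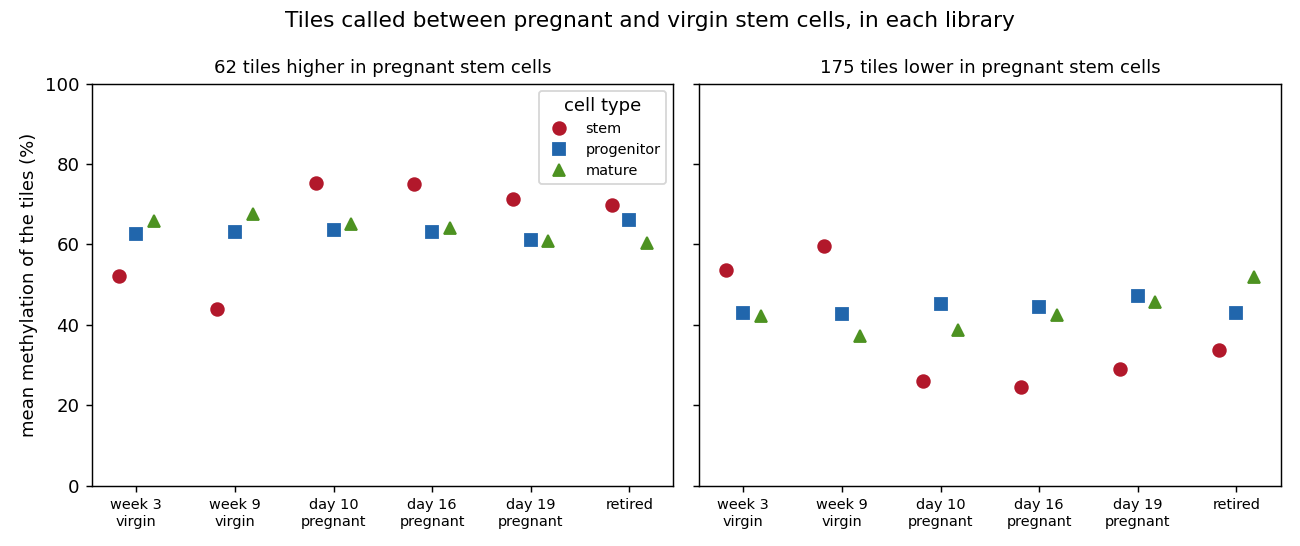
Mean methylation in percent (vertical axis) of the 62 tiles that rose (left) and the 175 tiles that fell (right) in pregnant against virgin stem cells, with 1 point per library, stages on the horizontal axis and markers for the cell type. The tiles were selected on the stem libraries; progenitor and mature libraries lie between the virgin and pregnant stem libraries, and the retired stem library lies at 69.9% in rising and 33.7% in falling tiles.

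Tiles are named by their mm9 position, and genes at these positions were not analysed here. The largest fall was on chromosome 14 at 75106001 to 75107000, where methylation was 88.4% ± 10.3 (SD, n = 2) in virgin and 27.8% ± 8.04 (n = 3) in pregnant stem libraries (adjusted p = 0.0400). On chromosome 15 at 25857001 to 25858000 it went from 86.4% ± 0.225 to 26.7% ± 4.43. The tile on chromosome 10 at 70512001 to 70513000 had 74.2% ± 10.2 in virgin and 15.3% ± 3.81 in pregnant stem cells. On chromosome 17 at 75432001 to 75433000 the levels were 69.3% ± 0.959 and 12.1% ± 3.05, and on chromosome 5 at 122975001 to 122976000 they were 77.0% ± 8.17 and 20% ± 12.2. The largest rise was on chromosome 9 at 47279001 to 47280000, from 32.3% ± 3.78 in virgin to 76.2% ± 4.94 in pregnant stem libraries (adjusted p = 0.0402). Methylation rose from 38.1% ± 12.3 to 79.0% ± 12.4 on chromosome 12 at 74495001 to 74496000, and from 15.4% ± 2.44 to 55.1% ± 6.96 on chromosome 11 at 98787001 to 98788000. Also on chromosome 11, at 117179001 to 117180000, it rose from 40.5% ± 3.97 to 79.8% ± 6.91. On chromosome 14 at 63524001 to 63525000 the levels were 50.2% ± 11.5 and 89.2% ± 1.55. Adjusted p at these 10 tiles was 0.0346 to 0.0480.

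Neither progenitor nor mature cells had a tile that passed the test between pregnant and virgin libraries. Progenitor cells had 2896 tiles (3.76%) and mature cells 3916 tiles (5.08%) at an unadjusted p under 0.05, against 11017 (14.3%) in stem cells; limma also called 0 in each. At the 237 stem cell tiles the change had the direction of stem cells in 35.02% of tiles in progenitor and 32.5% in mature cells, with median changes of -1.90 and -2.01 points on a scale where the stem cell median was 26.6. A difference of the pregnancy effect between cell types was tested directly and not shown: 0 tiles were called for stem against progenitor (8075 at an unadjusted p under 0.05, smallest adjusted p = 0.172), 0 for stem against mature (8811, 0.0738) and 0 for progenitor against mature (3589, 0.682), and 0 by limma. Without the week 3 virgin mature library, 28 tiles were called in mature cells and 1393 for the difference between stem and mature cells; without the week 3 virgin stem library, 53 tiles were called for that difference and 1 for stem against progenitor. Averaged over the cell types, 0 tiles were called between pregnant and virgin libraries (5031 at an unadjusted p under 0.05; limma 0).

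Whether methylation after past pregnancies lay with the pregnant or the virgin stages was asked in retired breeders, at the tiles called in stem cells. The retired stem library was nearer to the pregnant than to the virgin mean at 191 of 237 tiles, 80.6% (95% exact binomial interval 74.97 to 85.43%). In tiles of matched level that had not been called the share was 56.2%. The 237 tiles were selected for their virgin and pregnant stem levels, and at the same tiles the share was 30.4 to 76.4% in the 12 progenitor and mature libraries, highest in week 9 virgin mature. The retired stem library averaged 33.7% in the falling tiles, where pregnant stem libraries had 26.5%, and 69.9% in the rising tiles, where they had 73.9%. This is 1 library, with no replicate, and progenitor and mature cells had no called tiles to compare. Over the 3 cell types together, retired libraries gave 0 called tiles against virgin libraries (4078 at an unadjusted p under 0.05) and 0 against pregnant libraries (3722), where limma called 38 and 65. Retired libraries were 3 of the 7 whose files had the 6-column layout, so stage, layout and low depth cannot be told apart for them. Among virgin mice, week 9 and week 3 libraries differed at 0 tiles (4842 at an unadjusted p under 0.05; limma 0).

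The 3 cell types were compared over all stages, with stage as a block. Stem against progenitor cells gave 0 called tiles (7150 at an unadjusted p under 0.05, smallest adjusted p = 0.167), stem against mature cells 0 (8441, 0.0669) and progenitor against mature cells 0 (4594, 0.757); limma called 0 in each. In simulated counts with the same libraries, the test of stem against mature cells recovered 47% of tiles changed by 20 points. It recovered 90% of those set to change by 40 points, some of which were cut short.

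Similarity of the libraries was measured as Pearson's r across tiles after subtracting each tile's mean, where tiles are not independent replicates and unrelated libraries lie slightly below 0. Pairs with the same cell type label had a mean r of 0.001 (45 pairs), pairs of the same stage -0.087 (18 pairs) and other pairs -0.076 (90 pairs). Of all 7776 arrangements of the cell type labels within stages, 605 gave a mean same-label r as high as the deposited one (exact permutation p = 0.0778). The pregnant and retired stem libraries had r of 0.237 to 0.480 among themselves. The week 9 virgin progenitor library had r of 0.275 with week 3 virgin mature and 0.446 with day 16 pregnant mature, and these mature libraries had r of 0.409 with each other. The week 9 virgin mature library had r of 0.361 to 0.379 with the pregnant stem libraries, 0.221 with the retired stem library and -0.255 with the week 3 virgin mature library. Virgin stem libraries had r of 0.293 with each other and -0.291 to 0.068 with pregnant stem libraries. The most similar library had the same cell type label for 8 of 18 libraries, where 5.29 would be expected by chance.

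**Figure D3:**
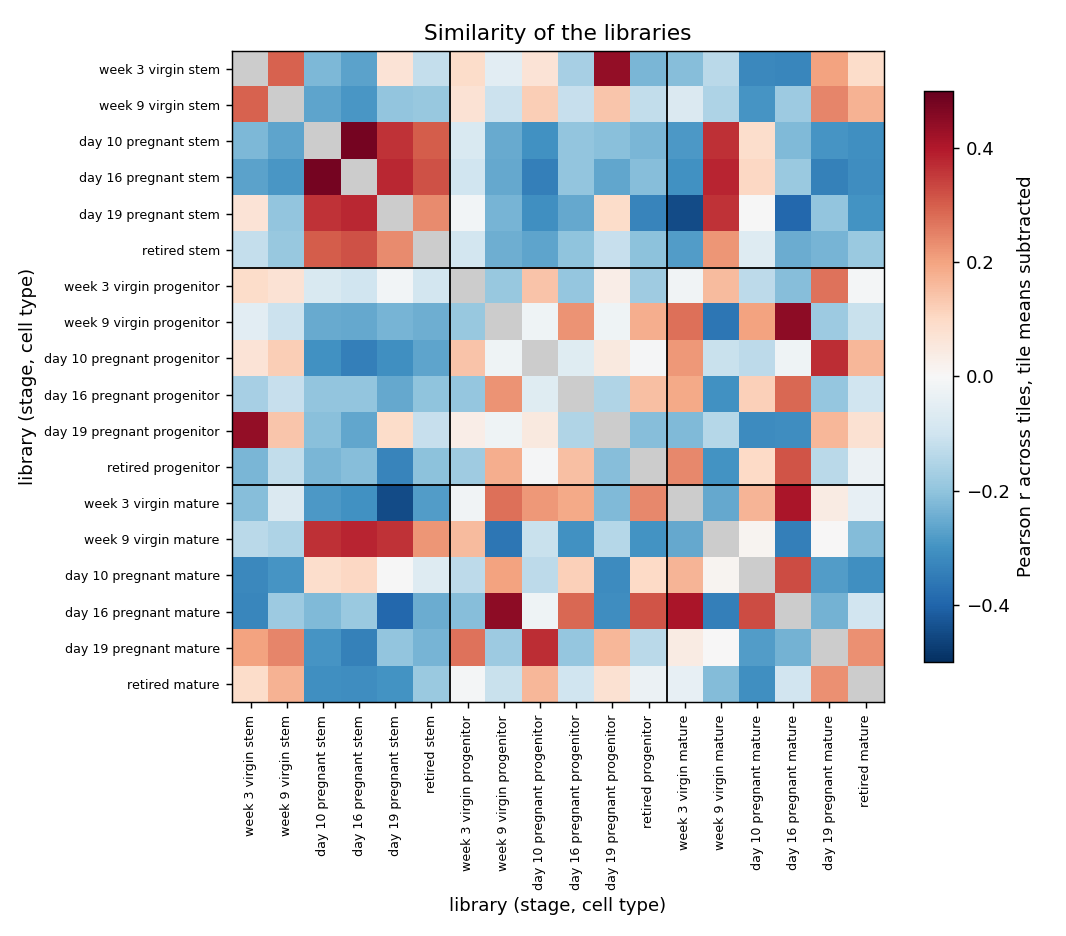
Pearson's r across 77064 tiles between the 18 libraries after subtraction of each tile's mean, with libraries ordered by cell type label and stage on both axes, black lines between cell types and the diagonal in grey. Pregnant and retired stem libraries have r of 0.237 to 0.480 with one another, and the week 9 virgin mature library has r of 0.361 to 0.379 with the pregnant stem libraries.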

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

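Both results below were singled out after their values were seen, because all pregnant libraries of one cell type lay on one side of the virgin libraries and all those of another cell type on the opposite side. At the 118570 CpGs with a mean level of 20 to 80%, all 3 pregnant stem libraries lay below both virgin stem libraries, by -4.84 points on average, and all 3 pregnant progenitor libraries lay above both virgin progenitor libraries, by 0.83 points. The difference of these effects was -5.67 points (exact permutation p = 0.1 over 10 splits, the smallest possible). At the tile on chromosome 12 from 74495001 to 74496000, pregnancy went with 40.9 points more methylation in stem cells and a difference of -14.1 points in mature cells, so that the effects differed by 55.1 points. The direct test of that difference at this tile missed the threshold (adjusted p = 0.088 with the moderated quasi-binomial model). No group had enough libraries to test for a single outlying one.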

How the results depend on the processing

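Of 296 alternative values for 24 results, 274 kept their side of the threshold or stayed within 1.5 times the count. The thinning, the 4-column files alone and the similarity settings were chosen after seeing the data. Tiles called between pregnant and virgin stem cells (237) fell to 43 with 10 reads, 26 in 500 bp tiles, 0 with limma and 0 with thinned reads, and rose to 441 with any CpG of 5 reads; leaving out 1 library gave 0 to 800. The 10-read setting changed the CpGs as well as the depth: 41610 tiles were tested, with 128 of the 237 among them. Thinning changed only the reads, and for limma the cause was not tested. In the 4-column files alone 184 tiles were called, 49 of them among the 237. Stem against mature cells gave 1 tile with 10 reads, 6 with no stage term and 0 to 2 with 1 library left out. Leaving out 1 library gave 0 to 28 tiles for pregnancy in mature cells, 0 to 1 and 0 to 1393 for the difference of the pregnancy effect between stem and progenitor and between stem and mature cells, and 0 to 1 for week 9 against week 3. The largest of these came without week 3 virgin mature, which left week 9 virgin mature as the only virgin mature library. With limma, retired libraries gave 38 tiles against virgin and 65 against pregnant libraries; the cause was not tested. On the log2 scale the mean same-label correlation was -0.040 and passed the threshold (exact permutation p = 0.0395). Tests of mean levels could not pass for pregnancy, nor for cell types with 1 stage left out (smallest possible p 0.0625). These therefore say nothing about stability although they count among the 274. Of 63 alternative mean differences, 6 changed sign, in 4 of 6 results that had missed their test. Among them were 0.608 points for stem minus progenitor and -0.431 points for pregnancy in progenitor cells. Both were with reads pooled over the shared CpGs. Tests of gene lists and promoters were not run.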

Other observations

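Chosen after the results were seen were the tests of exchanged labels, the test within the 4-column files and the exchanges of labels between libraries; the other tests of depth and of file layout, and those of recovery and of leaving out 1 library were set beforehand.

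Some pairs of libraries from different cell types and stages were as similar as the pregnant stem libraries were to each other. The week 3 virgin stem library was nearest to day 19 pregnant progenitor (r across tiles 0.440), and week 9 virgin progenitor to day 16 pregnant mature (r = 0.446). Chromosomes also differed: CpGs on the X chromosome averaged 76.1 to 78.1% methylation in the 18 libraries, against 47.9 to 49.9% on autosomes. Although all libraries were labelled female, 490 CpGs placed on the Y chromosome passed the coverage minimum in all 18.

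The tiles called between pregnant and virgin stem cells were set against exchanged labels, file layout and depth. The planned test of file layout decides nothing: day 10 and day 16 stem libraries, with the 4 columns of the virgin files, differed from the virgin mean by 1.15 times as much as the day 19 library, but all 237 tiles already separated the pregnant from the virgin libraries. Layout as the whole cause is argued against, since 184 tiles were called within the 4-column files (49 among the 237), and 214 without day 19 (117 among the 237), when all virgin and pregnant stem libraries compared had 4 columns. The count followed depth as set out beforehand for an effect of low depth. It fell from 3.08 to 1.03 called tiles per 1000 when 10 reads were required. Among tiles with a mean level of 20 to 80% it fell less in proportion, from 9.37 to 4.43 per 1000. The mix of tested tiles may thus account for part of the fall. In this class the median of the fewest reads was 55 in called and 48 in other tiles. Called tiles of this class were therefore not the shallower ones, though this difference was not tested. Of the 237 tiles, 128 were among those tested at 10 reads, and 40 were called at both settings. All 128 kept their direction, with a median change of 24.7 points against 25.1 at 5 reads, and 127 had an unadjusted p under 0.05. The reads at this setting had all been part of those that selected the tiles, so this is no independent test. It shows only that the change at these 128 tiles was also there without the shallowest CpGs. An effect of depth on which tiles pass the test stays open. The first test of exchanged labels met the bound set for it, with week 9 virgin mature at 0.666 on a scale from virgin (0) to pregnant stem (1) and 3 of 4 virgin progenitor and mature libraries at 0.5 or more, but 3 of 8 pregnant and retired ones were there too, so it separates nothing; 2 further tests were then chosen with that outcome known. At week 3 the higher mean correlation of the progenitor and mature libraries with pregnant stem libraries was -0.063. This argues against an exchange that made the calls by hiding a week 3 library like the pregnant stem ones. An exchange beside a real difference between virgin and pregnant stem cells would not be seen this way. At week 9 an exchange stays open: the mature library correlated with every pregnant stem library at 0.361 or more, above the 0.105 reached by other mature libraries. The week 9 stem library reached 0.2 with only 1 of the 5 other mature libraries. That decides nothing, since libraries labelled mature were not alike among themselves (mean r -0.039). Real differences between the stages were not excluded. An effect of age was not tested, since the labels give no age for the pregnant mice.

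The absence of called tiles between cell types was weighed in the same way. Leaving out any 1 library gave at most 2 called tiles in these comparisons. This argues against 1 library alone out of place hiding many called tiles. It cannot speak on an exchange between 2 libraries, where leaving out 1 keeps the other misplaced. Recovery with a library left out was not simulated. Too few reads or libraries may account for missed differences of 20 points, of which 47% were recovered in simulation (exact binomial interval 36.9 to 57.2%), too close to the bound of 50% to decide. Of differences set to 40 points, some of them cut short, 90% were recovered, in counts without any structure of stages or libraries. Exchanged labels cannot be told apart from stage differences: the share of arrangements as good as the deposited one was 0.0778, and 0.0395 on the log2 scale. Exchanging the stem and mature labels at week 9 alone would give 879 called tiles between stem and mature cells, which is a hypothesis about the week 9 pair found and tested on the same data, and no library was relabelled.

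No tile was called under the deposited labels in the comparisons below, so that every other split calls as many by necessity and the counts of splits say nothing about chance. For the cell types these were 32 of 32 exchanges within stages, with at most 0 tiles for stem against progenitor, 879 for stem against mature and 11 for progenitor against mature cells. For pregnancy averaged over cell types it was 100 of 100 drawn splits (highest 927), for retired against virgin libraries 27 of 27 (highest 145) and for retired against pregnant libraries 64 of 64 (highest 0). For week 9 against week 3 the 10 splits are too few for a share under 0.05, and the deposited split called 0 tiles. The highest other called 602, with both virgin stem libraries and week 3 virgin mature on the same side, so it mixes cell type with stage. In the splits with 145, 879 and 927 tiles, week 9 virgin mature lay on the side of the retired or pregnant stem libraries. In that with 602 it lay opposite both virgin stem libraries. The few splits that call 145 to 927 tiles may thus point to a structure of the libraries, which was not tested further. Pregnancy in stem cells, the only comparison with called tiles (237), was not set against other splits of its libraries. In other comparisons, groupings that were not the deposited ones called 602, 879 and 927 tiles. The grouping with 927 kept the deposited labels of all stem libraries, and that with 602 kept both virgin stem libraries together. That with 879 exchanged week 9 stem and mature. They therefore do not show how many tiles another split of the stem libraries would call. Whether the count of 237 sets the deposited stem cell labels apart from other groupings was not tested.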
